A study of Mus musculus with 10 samples.

How the data were processed

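The authors deposited 1 table of read counts per gene and 1 table of TPM for the 7 bulk libraries, and the count table was used for every main test. The deposited TPM equalled the counts over a length per gene, scaled to each library, with a largest log2 deviation of 1.2e-14 over the 17244 genes above 0 in all libraries. Per the submitters' processing notes, reads were checked with FastQC 0.11.9, trimmed with Trim Galore 0.6.5, aligned with STAR 2.7.4a to mm10 and counted with featureCounts 2.0.0. The annotation, the strand setting, the handling of reads that map to several places and the gene lengths were not given in the sources used here. Columns were matched to samples by name, and 0 columns belonged to other samples. The later TLSC 2C library is passage 13 in its column name and 14 in its label. Gene identifiers were matched to GENCODE vM21 (GRCm38), which named 55394 of 55573, and the 179 without a symbol held 0.0521% of counts.

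Genes passed edgeR filterByExpr, libraries were scaled by TMM (factors 0.839 to 1.11), and tests were edgeR quasi-likelihood F tests (edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3) with Benjamini-Hochberg adjustment, called at adjusted p under 0.05. All adjusted p-values of genes are from edgeR unless another tool is named. TLSC against ESC in 2i medium used the culture medium as the factor. Every TLSC library was in TPSC medium, the 2CLC library in KOSR and both ESC libraries in 2i. Effects of medium and of cell state could therefore not be told apart in any comparison between these kinds of library. The comparisons with mESC, 2CLC and rESC and between lines used all 7 libraries in 5 groups, so a lone library was assumed to vary as the other groups did, and the fold against rESC is the mean of the log2 folds of the 2 TLSC lines. In the fits in 5 groups, leaving out a TLSC library left the pair of the other TLSC line alone to give the spread. Counts of called genes and p-values of such fits were therefore not comparable with those of the full fit. The passage comparison used the 4 TLSC libraries with a term for the line. It had 1 residual degree of freedom, the difference in passage effect between the lines. CPM are counts relative to the TMM-scaled library total over genes that passed the filter, and SE is the absolute log2 fold over the square root of the edgeR F statistic. Where an arm had 0 counts the fold is a bound against a floor of 3 counts over that arm (0.0683 to 0.147 CPM in a single library), and where it had 1 to 3 counts the pooled ratio is given with an exact 95% interval. Such bounds and intervals cover counting error only.

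The 25 gene lists were fixed before the data were examined, as were the tests, their alternatives and the rule for named genes. The lists were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison, and with an estimated correlation as the alternative. Camera called 39 of 150 list tests with the preset, 37 with relative log expression scaling and 0 with estimated correlations. Named genes were those with the largest log2 fold each way among called genes with a mean of at least 5 CPM, arms that did not overlap and a symbol that was not a predicted or clone name, together with called members of called lists and 19 genes named in every comparison where measured. Comparisons of 1 library with 1 had no test and used log2 CPM with a prior count of 2, and the median of each list was placed among 10000 random lists matched on expression.

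On simulated counts with 200 changed genes, edgeR found 53% of genes changed by log2 2 in TLSC against ESC in 2i medium, 12% in TLSC C57/SPR against mESC, 3% against 2CLC, 11% against rESC, 29% between lines and 27% between passages. At log2 1 it found 6%, 1%, 0%, 1%, 1% and 4%. Its false calls were 7.81% in the first and 0 in the others, and those of DESeq2 ran from 12.7% to 50.9%. Each was a single simulation in which a gene had the same mean in all libraries and the trended spread of the fit in 5 groups. It held no differences between lines or passages, so the shares found can be too high where both lines form a single group. Changed genes were drawn from those with a mean above 5 CPM, so these shares do not cover genes of lower counts.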

Results

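The series held RNA sequencing of mouse embryonic stem cells (ESC) and of the totipotent-like stem cells (TLSC) its title names. Of its 10 samples, 7 were bulk libraries of polyadenylated RNA, and 3 were single-cell samples of embryo and placenta that were not analysed here. The bulk libraries comprised 4 TLSC libraries in the medium labelled TPSC, 1 library labelled 2CLC in KOSR medium, and 2 ESC libraries (mESC and rESC) in 2i medium, which holds 2 kinase inhibitors. The TLSC came from 2 lines, 2C (passages 8 and 14) and C57/SPR (passages 4 and 12), and the 2CLC and mESC libraries were also of C57/SPR. The line of rESC was not given. The labels did not say whether libraries of a group were separate cultures, so every p-value here measures only the spread between these samples.

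The libraries held 2.43e7 to 4.49e7 counts on 55573 genes, of which 23041 to 26796 had at least 1 count. Rank correlations between libraries were 0.969 for the 2C pair, 0.926 for the TLSC C57/SPR pair and 0.983 for mESC with rESC. The earlier TLSC C57/SPR library was about as close to 2CLC (0.923) as to the later one. Genes of the 2-cell (2C) embryo and genes linked to MERVL, the retrovirus active at that stage, took 1.36% and 1.41% of the counts of the earlier and later TLSC 2C libraries. The same list took 0.617% (95% binomial interval 0.614% to 0.620%) and 3.71% (3.70% to 3.72%) of the earlier and later TLSC C57/SPR libraries. It took 0.00675% (0.00650% to 0.00700%) of the 2CLC library, 0.000629% (0.000552% to 0.000713%) of mESC and 0.000906% (0.000820% to 0.000998%) of rESC. The later TLSC C57/SPR library also held 2.65% of its counts on processed pseudogenes (2.64% to 2.65%), against 1.05% to 1.20% in the other 6. These intervals covered counting error only.

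**Figure D1:**
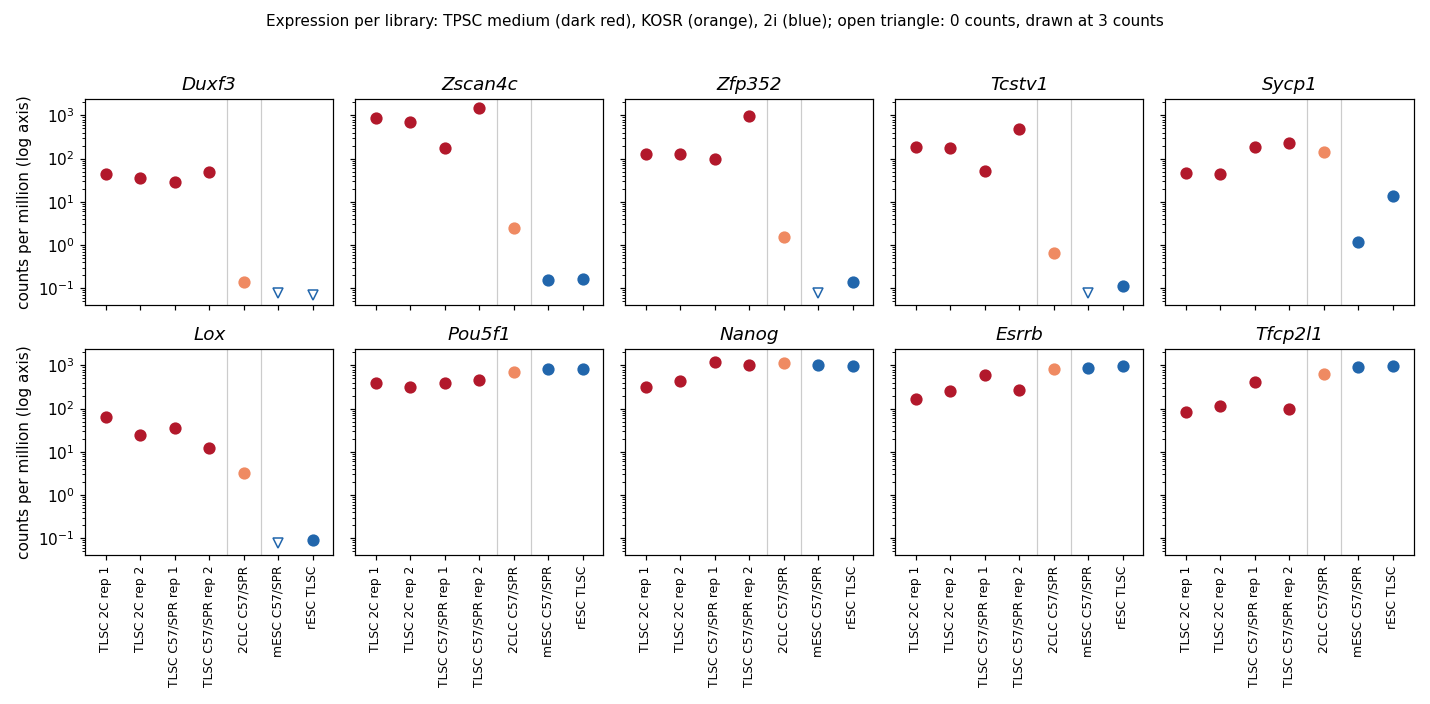
Expression of 10 genes in CPM (log axis) in each bulk library, among them Duxf3 at 39.1 ± 8.59 (SD, n = 4) in TLSC and 0 counts in both ESC libraries. An open triangle marks a library with 0 counts, drawn at 3 counts.

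In TLSC against ESC in 2i medium (4 libraries against 2), Duxf3, which encodes the DUX transcription factor that switches on 2-cell genes, rose from 0 counts in both ESC libraries to 39.1 ± 8.59 CPM (mean ± SD). That was at least 1072-fold (adjusted p = 0.00777), measured against a floor of 3 counts in the ESC libraries together. Zscan4c, of a zinc finger family that acts on telomeres in 2-cell-like cells, rose by log2 12.29 (SE 1.25, adjusted p = 0.0110; 809 ± 531 against 0.158 ± 0.00182 CPM). Zscan4d rose by log2 12.63 (SE 1.32, adjusted p = 0.0110; 964 ± 549 against 0.150 ± 0.0835 CPM). Zfp352, a zinc finger gene of the 2-cell embryo, rose by log2 12.08 (SE 1.98, adjusted p = 0.0159). Tcstv1 and Tcstv3, also of that stage, rose by 11.81 (SE 1.59, adjusted p = 0.0119) and 12.27 (SE 1.67, adjusted p = 0.0119). Zfp352 and Tcstv1 had 0 counts in mESC and 6 and 5 in rESC. Their log2 folds were 11.21 and 10.95 without mESC and 16.43 and 15.91 without rESC, so their size was uncertain. Pou5f1, which encodes the core pluripotency factor OCT4, fell by log2 1.07 (SE 0.23, adjusted p = 0.0304), from 817 ± 0.192 to 389 ± 60.5 CPM.

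Of 37 tested genes on the 2C and MERVL list 35 were higher and 0 lower (37 and 0 adjusted over the list alone), with a median log2 fold of 12.12, or 11.95 with floors for genes at 0. The list rose at adjusted p = 6.84e-52, and at adjusted p = 0.611 with an estimated correlation. AF067061, Spz1 (a germ cell transcription factor) and Ubtfl1 (an HMG-box gene of the early embryo) had 0 counts in ESC and rose at least 4908-fold (adjusted p = 0.0131), 2390-fold (adjusted p = 0.0164) and 2358-fold (adjusted p = 0.0110). Zscan4b rose 12967-fold (counting interval 3589 to 107079; adjusted p = 0.0110) against 2 counts in ESC. Copies of Zscan4, Tcstv and Usp17l share sequence and the files do not say how reads mapping to several places were counted, so the value of a single copy was uncertain.

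Fibroblast genes, the markers of feeder cells, moved with them: 12 of 18 were higher and 0 lower (15 and 0 over the list alone; median log2 4.75; adjusted p = 8.59e-10, and 0.611 with an estimated correlation). Lox, which encodes a collagen crosslinking enzyme, rose by log2 9.37 (SE 1.29, adjusted p = 0.0122; 33.9 ± 21.9 against 0.0456 ± 0.0644 CPM), and Acta2, a smooth muscle actin gene, rose 422-fold (117 to 3492; adjusted p = 0.0311) against 2 counts. Prrx1, a mesenchyme homeobox gene, and Lum, a matrix proteoglycan gene, had 0 counts in ESC and rose at least 76.8-fold (adjusted p = 0.0315) and 50.9-fold (adjusted p = 0.0218). Without the earlier 2C library these bounds were 41.6 and 32.1-fold and the ratio of Acta2 was 212. Prrx1, Lum and Acta2 lost their calls without the later 2C library (adjusted p = 0.0661, 0.0544 and 0.0643).

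Germline genes that DNA methylation silences rose too, 7 of 16 higher and 0 lower (13 and 0 over the list alone; median log2 3.71; adjusted p = 3.74e-09, and 0.611 with an estimated correlation). Among them Asz1 and Mov10l1, genes of the piRNA pathway, rose by log2 6.20 (SE 1.04, adjusted p = 0.0167) and 3.98 (SE 0.43, adjusted p = 0.0110). Taf7l, a germ cell transcription subunit gene, rose by log2 5.97 (SE 0.92, adjusted p = 0.0142) and Slc25a31, a testis ADP/ATP carrier gene, by 5.52 (SE 0.77, adjusted p = 0.0125).

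The list of core and naive pluripotency genes fell, with 2 of 23 higher and 4 lower (3 and 8 over the list alone; median log2 -0.99; adjusted p = 0.000476, and 0.675 with an estimated correlation). Tfcp2l1, a naive-state transcription factor gene, fell by log2 2.44 (SE 0.63, adjusted p = 0.0494), and Nr0b1, which encodes the nuclear receptor DAX1, by 2.08 (SE 0.41, adjusted p = 0.0246). Utf1, an ESC chromatin factor gene, fell by log2 1.13 (SE 0.27, adjusted p = 0.0432). Dppa2, an activator of Dux, moved the other way by log2 2.68 (SE 0.57, adjusted p = 0.0307). Esrrb (log2 -1.55, SE 0.47, adjusted p = 0.0730), Klf4 (-1.26, SE 0.49, adjusted p = 0.135) and Zfp42 (-1.19, SE 0.57, adjusted p = 0.200) were not called. Neither were Sox2 (-0.97, SE 0.41, adjusted p = 0.163) and Nanog (-0.41, SE 0.53, adjusted p = 0.626). Without the earlier TLSC C57/SPR library Esrrb (-2.01, adjusted p = 0.0187), Klf4 (-1.78, adjusted p = 0.0199) and Sox2 (-1.31, adjusted p = 0.0498) were called lower. In that fit 3 named genes gained a call and 5 lost theirs.

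Nuclear oxidative phosphorylation genes fell as a list with 0 of 29 higher and 1 lower (0 and 0 over the list alone; median log2 -0.52; adjusted p = 0.000500, and 0.710 with an estimated correlation). That 1 was Uqcrh, a complex III subunit gene (log2 -1.26, SE 0.26, adjusted p = 0.0292). Ribosomal protein genes fell as a list with 0 of 82 called (median log2 -0.20; adjusted p = 0.00719, and 0.790 with an estimated correlation), a call lost without the earlier TLSC C57/SPR library (adjusted p = 0.290).

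The other 19 lists were not called. Among developmental lists, 6 trophoblast genes were higher and 2 lower (median log2 1.64, adjusted p = 0.195), against 5 and 1 for primitive endoderm (1.86, adjusted p = 0.263) and 2 and 0 for germ layers (1.33, adjusted p = 0.233). Gata6, a master gene of primitive endoderm, rose by log2 5.31 (SE 1.35, adjusted p = 0.0490), while Gata3 and Cdx2 of trophoblast had means under 1.0 CPM in both arms and were not called (adjusted p = 0.541 and 0.786). Gata6 lost its call without the later 2C library (adjusted p = 0.0849) and without the earlier or later TLSC C57/SPR library (0.0684 and 0.0527). Oocyte and maternal-effect genes gave 2 higher and 0 lower (2.51, adjusted p = 0.205), formative and primed pluripotency genes 1 and 0 (1.79, adjusted p = 0.0821, but 0.00985 without the later TLSC C57/SPR library, and 0.601 there with an estimated correlation). Imprinted genes gave 7 and 2 (1.36, adjusted p = 0.183), and Xist with Y-linked genes 0 and 0, or 4 and 0 over the list alone (11.77, or 8.71 with floors, adjusted p = 0.195). The Y-linked values came from line 2C and did not tell TLSC from ESC. Eif2s3y had 2006 and 2235 counts in TLSC 2C, 0 and 2 in TLSC C57/SPR and 0 in both ESC libraries. DNA methylation enzymes had 0 called (0.27, adjusted p = 0.777), with Dnmt3b at log2 0.58 (SE 1.02, adjusted p = 0.724) and Dnmt3l at -0.68 (SE 0.33, adjusted p = 0.203). The DOT1L and KDM5 list also had 0 called (0.30, adjusted p = 0.700). Dot1l, the target of the inhibitor SGC0946 in the treatment protocol, stood at log2 0.37 (SE 0.32, adjusted p = 0.452) and Kdm5b at 0.82 (SE 0.25, adjusted p = 0.0771).

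Among pathway lists, repressors of the 2C programme had 2 higher and 1 lower (median log2 -0.22, adjusted p = 0.241), JAK/STAT3 genes 1 and 0 (-0.16, adjusted p = 0.349), and WNT targets 2 and 1 (0.66, adjusted p = 0.875). ERK targets had 2 and 0 (0.47, adjusted p = 0.349) and p53 targets 4 and 1 (0.54, adjusted p = 0.517). Glycolysis had 1 and 0 (0.30, adjusted p = 0.700), cell cycle 3 and 0 (0.46, adjusted p = 0.670), and stress response 2 and 1 (0.26, adjusted p = 0.429). Interferon-stimulated genes had 2 and 1 (1.97, or 1.68 with floors, adjusted p = 0.349) and mitochondrially encoded genes 0 and 0 (-0.10, adjusted p = 0.254, but lower at 0.00985 without the later TLSC C57/SPR library, and 0.601 there with an estimated correlation).

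Outside the lists, BB287469, Fam90a1a, Tacr3 (a neurokinin receptor gene), Ighv1-60 (annotated as an immunoglobulin pseudogene) and Olfr376 (an olfactory receptor gene) went from 0 counts to between 52.1 ± 43.5 and 68.8 ± 67.6 CPM. These were rises of at least 1883, 1831, 1781, 1776 and 1426-fold (adjusted p = 0.0139, 0.0199, 0.0136, 0.0171 and 0.0134). BC147527 rose 15656-fold (2810 to 618393; adjusted p = 0.0134). Without the later TLSC C57/SPR library the first 5 bounds fell to 974, 670, 1068, 732 and 866-fold and the ratio to 7709, and the bounds of AF067061 and Spz1 to 2643 and 1124-fold. Among named genes Trpm1, a cation channel gene of retina and melanocytes, fell most, from 209 ± 59.5 to 4.08 ± 2.62 CPM (log2 -5.68, SE 0.62, adjusted p = 0.0110). Ubd, a ubiquitin-like modifier gene (log2 -4.88, SE 0.50, adjusted p = 0.0110), and Mybpc3, of cardiac muscle (-4.81, SE 0.93, adjusted p = 0.0237), also fell. H2-T3, a class I histocompatibility gene (-4.51, SE 0.54, adjusted p = 0.0111), and Nkx6-2, a neural homeobox gene (-4.42, SE 0.50, adjusted p = 0.0110), were lower as well. So were Ppp1r14d, a phosphatase inhibitor gene (-4.37, SE 0.49, adjusted p = 0.0110), and Islr2 and Lrrn2, of neuronal surface proteins (-4.21, SE 0.64, adjusted p = 0.0139, and -4.15, SE 0.88, adjusted p = 0.0302). Lower too were Pmel, of melanosomes (-3.98, SE 0.65, adjusted p = 0.0156), and Gjb4, a connexin gene (-3.93, SE 0.71, adjusted p = 0.0194). In all, 1842 of 23184 genes were higher and 703 lower, and 137 processed pseudogenes were higher and 1 lower of 2006. Without mESC or without rESC edgeR called 0 genes, with 3743 and 3765 at unadjusted p under 0.05 and 2910 and 2835 called by DESeq2, and all 41 of the named genes called here lost their call. The count was 1496 without the earlier and 935 without the later 2C library (4 and 11 named genes lost). It was 2274 without the earlier TLSC C57/SPR library (5 lost, among them Gata6 at adjusted p = 0.0684 and Utf1 at 0.0680) and 4364 without the later, where Tfcp2l1 and Gata6 lost theirs. Pou5f1 lost its call in 5 of these 6 fits, with its log2 at -1.08 to -0.95 in them (adjusted p = 0.241 without mESC, 0.234 without rESC, 0.0607 and 0.0914 without the earlier and later 2C library, and 0.0516 without the earlier TLSC C57/SPR library).

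**Figure D2:**
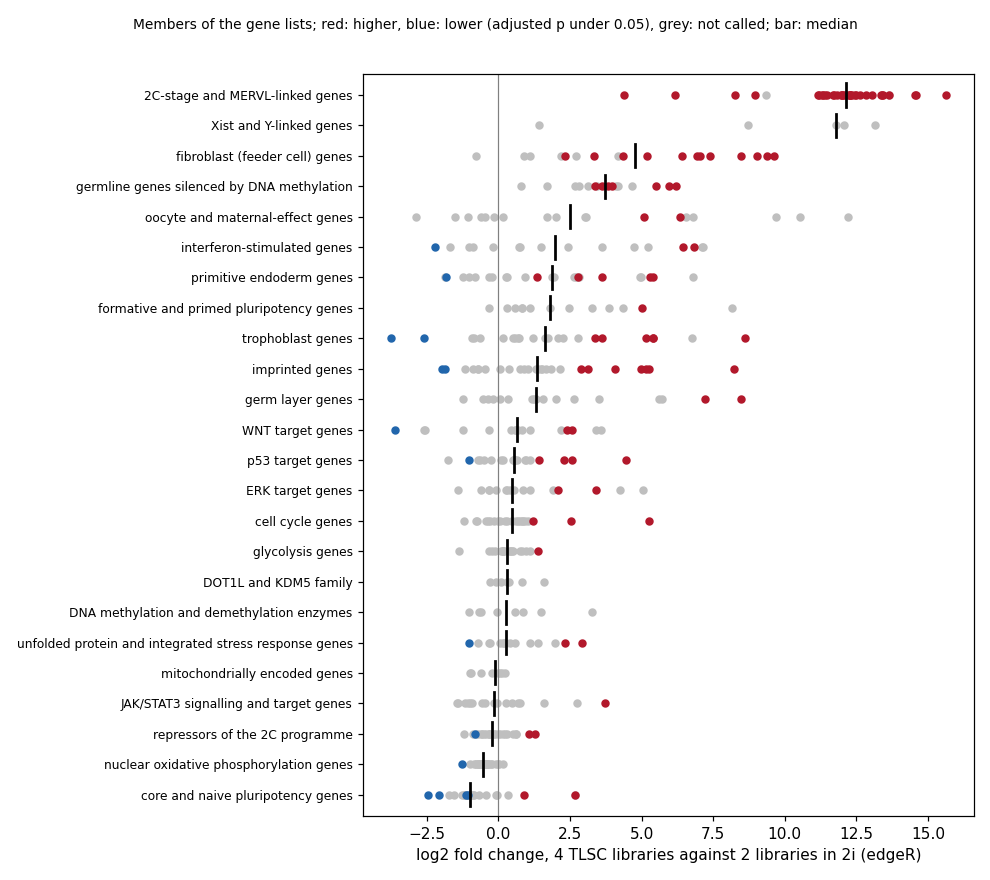
Log2 fold changes of the members of 24 gene lists in TLSC against ESC in 2i medium, with a bar at each median (12.12 for the 2C and MERVL list, 4.75 for fibroblast genes). Members called higher or lower are red or blue.

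Within line C57/SPR, TLSC against mESC (2 libraries against 1), Sycp1, which encodes the backbone of the meiotic synaptonemal complex, rose from 1.15 to 210 ± 31.2 CPM (log2 7.51, SE 0.70, adjusted p = 0.00536). Stra8, needed for entry into meiosis, rose from 0.235 to 54.1 ± 3.80 CPM (log2 7.82, SE 0.91, adjusted p = 0.00646). Zscan4c rose by log2 12.32 (SE 1.70, adjusted p = 0.00646) and Zscan4d by 11.74 (SE 1.57, adjusted p = 0.00646). Zfp352, Tcstv1 and Duxf3 had 0 counts in mESC and rose at least 6667-fold (adjusted p = 0.00646), 3468-fold (adjusted p = 0.00646) and 487-fold (adjusted p = 0.00580). Tcstv3 rose 7407-fold (2534 to 35918; adjusted p = 0.00664). Trpm1 fell by log2 4.72 (SE 0.48, adjusted p = 0.00610), from 166 to 6.30 ± 0.863 CPM.

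The 2C and MERVL list had 36 of 37 genes higher and 0 lower (37 and 0 over the list alone; median log2 13.57, or 12.19 with floors; adjusted p = 2.25e-42, and 0.778 with an estimated correlation). Zscan4a, annotated as a pseudogene, reached 1305 ± 1437 CPM (at least 16634-fold, adjusted p = 0.00646), and Tdpoz3 and Zscan4f rose at least 6662-fold and 5203-fold (adjusted p = 0.00646 for both). Fibroblast genes had 12 of 18 higher and 0 lower (15 and 0 over the list alone; median 6.57, or 4.41 with floors; adjusted p = 2.79e-11, and 0.778 with an estimated correlation). The collagen gene Col3a1 rose at least 312-fold (adjusted p = 0.00646), Lox at least 304-fold (adjusted p = 0.00646), Postn, of a matrix protein, at least 39.0-fold (adjusted p = 0.0129) and Col1a2 710-fold (196 to 5863; adjusted p = 0.00646). Without the earlier TLSC C57/SPR library these folds were 202, 156, 27.5 and 358. The germline list had 12 of 16 higher and 0 lower (14 and 0 over the list alone; median 4.53; adjusted p = 5.86e-17, and 0.284 with an estimated correlation). Its genes included Tdrd1, of the piRNA pathway (at least 92.6-fold, adjusted p = 0.00750, but 58.9-fold without the later library), and Slc25a31 (log2 7.18, SE 0.97, adjusted p = 0.00646).

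The pluripotency list fell with 1 of 23 higher and 0 lower (2 and 0 over the list alone; median log2 -0.62; adjusted p = 0.0227, and 0.778 with an estimated correlation). Dppa2 was the higher gene (log2 3.03, SE 0.76, adjusted p = 0.0430), and Pou5f1 (-0.95, SE 0.46, adjusted p = 0.279) and Nanog (0.13, SE 0.49, adjusted p = 0.921) were not called. Oxidative phosphorylation genes fell with 0 of 29 called (median -0.32; adjusted p = 0.0124, and 0.868 with an estimated correlation). Both calls depended on the earlier TLSC C57/SPR library (adjusted p = 0.0662 and 0.774 without it), and the first also on the later library (0.0531). Ribosomal protein genes, not called here (median -0.02, adjusted p = 0.0869), rose without the earlier library (0.55, adjusted p = 2.06e-06) and fell without the later (-0.92, adjusted p = 1.31e-20). With an estimated correlation these stood at 0.865 and 0.801.

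Gata6 rose 147-fold (40.4 to 1216; adjusted p = 0.0284), or 85.3-fold without the earlier library. Abca12, a lipid transporter gene, Zscan4b, Trim75 and BC147527 rose at least 6609, 4918, 4677 and 4535-fold (adjusted p = 0.00646, 0.00646, 0.00646 and 0.00725). The later library carried most of these bounds: without it those of Abca12, Zscan4b, Trim75 and BC147527 were 1325, 1106, 946 and 562-fold. Likewise those of Zscan4a, Zfp352, Tdpoz3, Zscan4f and Tcstv1 were 3677, 1228, 2080, 1234 and 648-fold, and the ratio of Tcstv3 was 1498. Besides Trpm1, large falls among named genes were of Ubd (log2 -5.68, SE 0.72, adjusted p = 0.00646), Lrrn2 (-5.01, SE 1.05, adjusted p = 0.0210), H2-T3 (-4.74, SE 0.76, adjusted p = 0.00780) and Tlx2, a homeobox gene (-4.62, SE 0.75, adjusted p = 0.00791). Egfl6, of a matrix protein (-4.40, SE 0.70, adjusted p = 0.00737), Rerg, a Ras-like gene (-4.21, SE 0.68, adjusted p = 0.00783), and Aldh1a3, a retinoic acid synthesis gene (-4.19, SE 0.75, adjusted p = 0.0112), fell as well. Dnmt3b was not called (-1.50, SE 0.66, adjusted p = 0.236). In total 1365 genes were higher and 177 lower. The lone mESC library was assumed to vary as the 2 TLSC lines did. Without the earlier or the later TLSC C57/SPR library, which left a single library in each arm, Dnmt3b stood at log2 -2.45 or -0.97. Pou5f1 stood at -0.80 or -1.13 in these fits.

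TLSC C57/SPR against the library labelled 2CLC of the same line (2 against 1) was higher in 2C genes. The labels did not say what share of the cells of the 2CLC library was in the 2-cell-like state, or whether they were sorted. Usp17lb, of a deubiquitinase family expressed at the 2-cell stage, rose from 3.83 to 2077 ± 2258 CPM (log2 9.08, SE 1.42, adjusted p = 0.0235). Zscan4c rose from 2.51 to 819 ± 910 CPM (8.35, SE 1.41, adjusted p = 0.0235) and Duxf3 from 0.142 to 38.2 ± 13.8 CPM (8.04, SE 0.90, adjusted p = 0.0235). The earlier and later TLSC C57/SPR libraries stood at 481 and 3674 CPM for Usp17lb and at 176 and 1463 CPM for Zscan4c. Dppa3, a maternal factor that protects DNA methylation, rose from 34.5 to 656 ± 557 CPM (4.25, SE 0.95, adjusted p = 0.0456). Cdhr2, a cadherin gene of the brush border, fell from 27.8 to 0.683 ± 0.551 CPM (-5.30, SE 0.81, adjusted p = 0.0235).

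On the 2C and MERVL list 36 of 37 genes were higher and 0 lower (37 and 0 over the list alone; median log2 8.55; adjusted p = 1.81e-48, and 0.744 with an estimated correlation). Spz1 rose by log2 10.27 (SE 1.85, adjusted p = 0.0240), Usp17ld by 9.52 (SE 1.49, adjusted p = 0.0235), and Tdpoz3 by 9.22 (SE 1.27, adjusted p = 0.0235). Tcstv1 rose by 8.68 (SE 1.50, adjusted p = 0.0235), Tcstv3 by 8.52 (SE 1.55, adjusted p = 0.0240), Zfp352 by 8.41 (SE 1.48, adjusted p = 0.0235) and Zscan4d by 7.72 (SE 1.30, adjusted p = 0.0235). The pluripotency list fell (median -0.45, with 1 higher and 0 lower; adjusted p = 0.0354) and the fibroblast list rose (1.26, with 0 called; adjusted p = 0.0382), both at 0.744 with an estimated correlation. Without the earlier TLSC C57/SPR library these calls were lost (adjusted p = 0.122 and 0.209). The germline list was not called (1 higher, 0 lower, median 0.39, adjusted p = 0.251).

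Ighv1-60, Nek10 (a kinase gene), Obox5 (an oocyte homeobox gene), Ciita (the class II histocompatibility activator gene), Olfr881, Olfr815, AA414992 and Cpxcr1 had 0 counts in 2CLC. They rose at least 1403, 1014, 467, 443, 441, 361, 289 and 261-fold (adjusted p = 0.0235, 0.0235, 0.0253, 0.0235, 0.0240, 0.0235, 0.0235 and 0.0463). Without the later TLSC C57/SPR library these bounds were 279, 202, 72.7, 112, 74.0, 70.2, 67.7 and 38.2-fold. Slc38a5, an amino acid transporter gene (log2 -4.15, SE 0.78, adjusted p = 0.0254), Rerg (-4.01, SE 0.68, adjusted p = 0.0235), Tlx2 (-3.75, SE 0.74, adjusted p = 0.0289) and Mcf2, a nucleotide exchange factor gene (-3.14, SE 0.62, adjusted p = 0.0292), fell. So did Cited4, a transcription cofactor gene (-3.04, SE 0.60, adjusted p = 0.0284), Slc51a, a bile acid transporter gene (-2.95, SE 0.63, adjusted p = 0.0371), and Nefm, a neurofilament gene (-2.85, SE 0.57, adjusted p = 0.0296). Pou5f1 (-0.75, SE 0.47, adjusted p = 0.561) and Sox2 (-0.48, SE 0.60, adjusted p = 0.832) were not called. Over all genes 614 were higher and 15 lower. Without the earlier TLSC C57/SPR library, which left a single library in each arm, Sox2 moved to log2 -1.35. Esrrb, Klf4 and Dnmt3b stood at -1.56, -1.93 and -2.08 in that fit. Without the earlier or later library ribosomal protein genes, not called here (adjusted p = 0.364), rose (adjusted p = 4.88e-10) or fell (3.27e-22), and oxidative phosphorylation genes fell without the later (1.29e-09). With an estimated correlation the adjusted p was 0.840 without the earlier and 0.776 without the later.

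In TLSC of both lines against rESC (4 against 1), Trpm1 fell by log2 6.20 (SE 0.38, adjusted p = 0.000322), from 251 to 4.08 ± 2.62 CPM. These folds average the 2 lines in log2 and can lie apart from the ratio of the means. Tlx2 fell from 60.2 to 1.13 ± 1.65 CPM, a log2 ratio of means of -5.73 (adjusted p = 0.00170). Its fitted log2 of -8.19 rested on 1 count in TLSC 2C, against 138 in TLSC C57/SPR. Magel2, an imprinted gene that acts in protein recycling, rose by log2 7.75 (SE 1.15, adjusted p = 0.00470; 43.9 ± 25.1 against 0.182 CPM). Sox3, a SoxB1 factor gene of the epiblast and neural tissue, rose by 4.71 (SE 0.66, adjusted p = 0.00383; 42.6 ± 32.4 against 1.23 CPM). Duxf3 rose at least 573-fold (adjusted p = 0.00170) from 0 counts, Zscan4d by log2 13.27 (SE 1.66, adjusted p = 0.00298) and Zscan4c by 12.28 (SE 1.67, adjusted p = 0.00357).

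All 37 genes of the 2C and MERVL list were higher (37 over the list alone; median log2 11.85, or 10.88 with floors; adjusted p = 1.03e-42, and 0.680 with an estimated correlation). AF067061 rose at least 2623-fold (adjusted p = 0.00470), Spz1 at least 1277-fold (adjusted p = 0.00666) and Ubtfl1 at least 1260-fold (adjusted p = 0.00298). Tcstv3, Tcstv1 and Zfp352 rose by log2 11.85 (SE 1.82, adjusted p = 0.00523), 10.88 (SE 1.68, adjusted p = 0.00527) and 10.85 (SE 1.67, adjusted p = 0.00527). The fibroblast list rose with 11 of 18 higher and 0 lower (14 and 0 over the list alone; median 4.21; adjusted p = 3.76e-09, and 0.680 with an estimated correlation). Acta2 rose at least 148-fold (adjusted p = 0.00651), Prrx1 at least 41.0-fold (adjusted p = 0.0300), Lum at least 27.2-fold (adjusted p = 0.0227) and Lox by log2 8.42 (SE 1.25, adjusted p = 0.00470). The germline list rose with 9 of 16 higher and 0 lower (15 and 0 over the list alone; median 2.96; adjusted p = 8.14e-10, and 0.494 with an estimated correlation). Asz1 stood at log2 6.76 (SE 0.89, adjusted p = 0.00342), Taf7l at 5.36 (SE 0.96, adjusted p = 0.00822), Slc25a31 at 4.80 (SE 0.81, adjusted p = 0.00651) and Mov10l1 at 3.76 (SE 0.69, adjusted p = 0.00920).

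The pluripotency list fell with 1 of 23 higher and 5 lower (2 and 12 over the list alone; median log2 -1.19; adjusted p = 4.79e-05, and 0.523 with an estimated correlation). Tfcp2l1 fell by log2 2.62 (SE 0.57, adjusted p = 0.0198), and Nr0b1 by 2.46 (SE 0.37, adjusted p = 0.00470). Tbx3, a self-renewal T-box gene, fell by log2 2.09 (SE 0.37, adjusted p = 0.00820; -1.23 as the ratio of means) and Zfp42, a marker of the naive state, by 1.41 (SE 0.39, adjusted p = 0.0477). Dppa2 rose by 2.63 (SE 0.72, adjusted p = 0.0463). Esrrb (-1.72, SE 0.48, adjusted p = 0.0503) and Pou5f1 (-1.08, SE 0.41, adjusted p = 0.132) were not called. Formative and primed genes rose with 6 of 13 higher and 0 lower (6 over the list alone; median 1.87; adjusted p = 0.00273, and 0.799 with an estimated correlation). They included Fgf5, a signal of the primed epiblast (at least 119-fold, adjusted p = 0.0228, but 22.1-fold without the earlier 2C library), and the epiblast factor genes Pou3f1 (log2 4.48, SE 0.90, adjusted p = 0.0135) and Otx2 (3.37, SE 0.84, adjusted p = 0.0334). Imprinted genes rose with 5 of 26 higher and 2 lower (10 and 2 over the list alone; median 1.29; adjusted p = 0.0330, and 0.799 with an estimated correlation). Examples were the growth inhibitor Cdkn1c (4.76, SE 0.93, adjusted p = 0.0122), the noncoding H19 (4.67, SE 0.70, adjusted p = 0.00479) and the placental Peg10 (4.39, SE 0.71, adjusted p = 0.00598). The lines stood apart in several of these genes. Tbx3 had 31.2 CPM in TLSC 2C and 348 in TLSC C57/SPR. The reverse held for Fgf5 (15.7 and 0.508 CPM), Pou3f1 (104 and 12.6), Otx2 (28.4 and 3.11) and Peg10 (871 and 158). No ESC library was labelled as of line 2C, so line and TLSC state could not be told apart in the 2C values. Without the earlier TLSC C57/SPR library the formative and imprinted calls were lost (adjusted p = 0.0779 and 0.0733), the latter also without the earlier 2C library (0.127).

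Xist and Y-linked genes rose with 4 of 5 higher and 0 lower (4 over the list alone; median log2 8.74, or 7.66 with floors; adjusted p = 0.000973, and 0.523 with an estimated correlation). Eif2s3y, a Y-linked translation factor gene, was at least 470-fold higher (adjusted p = 0.0141), Ddx3y, a helicase gene, 223-fold (adjusted p = 0.0215), and the demethylase genes Kdm5d and Uty 182-fold (adjusted p = 0.00651) and 174-fold (adjusted p = 0.00695). The 2C line carried these means: Eif2s3y had 2006 and 2235 counts in TLSC 2C, 0 and 2 in TLSC C57/SPR and 0 in rESC. These values set the 2C line apart and did not tell TLSC from ESC. With a single 2C library left out the bounds were as low as 285, 145, 118 and 114-fold. This list call was lost without the later TLSC C57/SPR library (adjusted p = 0.151). Oxidative phosphorylation genes fell with 0 of 29 called (median -0.55; adjusted p = 0.00670, and 0.843 with an estimated correlation). Ribosomal protein genes fell with 0 higher and 1 lower (median -0.24; adjusted p = 0.0330, and 0.865 with an estimated correlation), the lower gene being the muscle-specific Rpl3l (log2 -2.36, SE 0.59, adjusted p = 0.0335). The list call was lost without the later 2C library (adjusted p = 0.0774) or the earlier TLSC C57/SPR library (0.714), and with relative log expression scaling (0.0559).

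BB287469 and Tacr3 rose at least 1006 and 952-fold (adjusted p = 0.00535 and 0.00609), or 521 and 571-fold without the later TLSC C57/SPR library, where the bounds of AF067061 and Spz1 were 1413 and 601-fold. Without the earlier 2C library those of Acta2, Prrx1 and Lum were 66.9, 22.2 and 17.2-fold. Vax2, an eye homeobox gene (log2 -5.67, SE 0.60, adjusted p = 0.00191; -3.18 as the ratio of means, with 4 counts in TLSC 2C and 406 in TLSC C57/SPR), Mybpc3 (-5.33, SE 0.50, adjusted p = 0.00170) and Kbtbd11, a kelch-repeat gene (-4.75, SE 0.81, adjusted p = 0.00680), fell. Together 1432 genes were higher and 800 lower. Without the later TLSC C57/SPR library, which left that line a single library, Eif2s3y and Ddx3y lost their calls. Their folds stayed at log2 7.12 and 6.59 and had no SE, so the loss did not mean that the difference was gone. Without the earlier 2C library Zfp42 (adjusted p = 0.337) and Rpl3l (0.134) were lost, and without the later 2C library these 2 with Tbx3 (0.0702) and Otx2 (0.0653).

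Between the TLSC lines, 2C against C57/SPR (2 against 2), Dnmt3b, a de novo DNA methyltransferase gene, was higher in 2C by log2 2.95 (SE 0.61, adjusted p = 0.0193), at 801 ± 422 against 103 ± 72.2 CPM. Tbx3 was lower by 3.48 (SE 0.41, adjusted p = 0.00117), at 31.2 ± 3.25 against 348 ± 0.922 CPM. Dazl, an RNA-binding germ cell gene, was lower by 3.10 (SE 0.41, adjusted p = 0.00207), at 50.5 ± 7.23 against 432 ± 47.4 CPM. Otx2 was higher by log2 3.18 (SE 0.64, adjusted p = 0.0171), at 28.4 ± 5.12 against 3.11 ± 2.05 CPM. Without the earlier 2C library Dnmt3b stood at log2 2.28 (adjusted p = 0.0860) and 8 other named genes given below lost their calls. These were Fgf5 (log2 2.79, adjusted p = 0.551), Pou3f1 (1.86, adjusted p = 0.373), Stra8 (-2.14, adjusted p = 0.261), Sycp1 (-2.24, adjusted p = 0.189), Prdm14 (0.485), Zfp42 (0.626), Cdkn1c (0.138) and Nnat (0.123). Without the later 2C library 5 did: Otx2 (adjusted p = 0.0578), Peg10 (0.0616), Sycp1 (0.188), Cdkn1c (0.168) and Zfp42 (0.312).

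Formative and primed genes were higher in 2C, 7 of 13 with 0 lower (10 and 0 over the list alone; median log2 2.22; adjusted p = 1.30e-08, and 0.777 with an estimated correlation). Fgf5 (4.95, SE 1.02, adjusted p = 0.0196), Pou3f1 (3.05, SE 0.63, adjusted p = 0.0194) and Zic2, a zinc finger gene of the epiblast (2.99, SE 0.60, adjusted p = 0.0171), were among them. The pluripotency list was lower, 0 of 23 higher and 3 lower (2 and 7 over the list alone; median -0.99; adjusted p = 0.00440, and 0.556 with an estimated correlation; 0.0879 without the earlier 2C library). Its lower genes included Prdm14, a germ cell and naive-state regulator (-2.17, SE 0.50, adjusted p = 0.0342), and Zfp42 (-1.78, SE 0.39, adjusted p = 0.0266), while Nanog was not called (-1.56, SE 0.41, adjusted p = 0.0561).

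Germline genes were lower in 2C, 0 of 16 higher and 3 lower (0 and 5 over the list alone; median log2 -1.07; adjusted p = 0.000729, and 0.556 with an estimated correlation). Stra8 stood at -2.59 (SE 0.50, adjusted p = 0.0147) and Sycp1 at -2.19 (SE 0.39, adjusted p = 0.00990). Imprinted genes were higher, 3 of 26 with 0 lower (8 and 0 over the list alone; median 0.60; adjusted p = 0.000749, and 0.870 with an estimated correlation). These were Cdkn1c by 2.58 (SE 0.62, adjusted p = 0.0391), Peg10 by 2.46 (SE 0.49, adjusted p = 0.0171) and Nnat, a neuronal membrane gene, by 2.36 (SE 0.45, adjusted p = 0.0127). The list of Xist and Y-linked genes was higher, 4 of 5 with 0 lower (4 over the list alone; median 8.05; adjusted p = 4.03e-11, and 0.468 with an estimated correlation). Eif2s3y stood 1708-fold (472 to 14105; adjusted p = 0.000313) and Ddx3y 819-fold (226 to 6764; adjusted p = 0.000588) above 2 counts in C57/SPR. Kdm5d and Uty differed by log2 8.05 (SE 0.79, adjusted p = 0.000460) and 7.89 (SE 0.81, adjusted p = 0.000527).

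The 2C and MERVL list was not called between the lines (0 higher and 4 lower, 0 and 7 over the list alone; median log2 -0.84; adjusted p = 0.0931). Duxf3 (0.07, SE 0.46, adjusted p = 0.965) and Zscan4c (-0.04, SE 0.74, adjusted p = 0.989) had values near 0. Without the earlier TLSC C57/SPR library, which left that line a single library, this list was lower in 2C (median -1.62). Without the later it was higher (1.18), and ribosomal protein genes changed direction in the same way. With an estimated correlation both lists stood at adjusted p = 0.695 and 0.854 in these fits.

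Cst9 (a cystatin gene), Ccr8 (a chemokine receptor gene) and Usp9y (a Y-linked deubiquitinase gene) had 0 counts in C57/SPR and were at least 548, 421 and 368-fold higher in 2C (adjusted p = 0.000377, 0.000496 and 0.000570). Psg20 (a pregnancy-specific glycoprotein gene), Ighv11-2, Tex13c1, Vmn2r20 and Ighv11-1 had 0 counts in 2C and were at least 1227, 1100, 349, 341 and 331-fold lower (adjusted p = 0.00221, 0.00370, 0.00654, 0.00352 and 0.00682). Without the later TLSC C57/SPR library the last 5 bounds were 238, 150, 57.9, 93.8 and 55.2-fold. By totals 292 genes were higher and 987 lower, and among 2006 processed pseudogenes 19 were higher and 411 lower. With 1 library of either line left out, the spread came from the pair of the other line alone, so totals of such fits were not comparable with these.

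**Figure D3:**
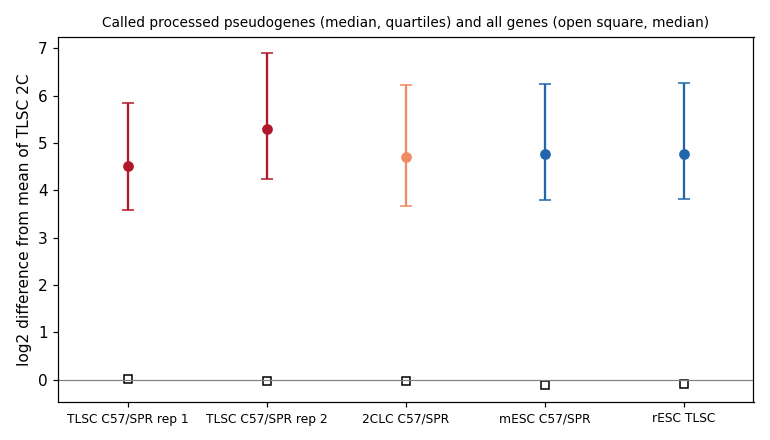
Log2 difference in CPM from the TLSC 2C mean of the 411 processed pseudogenes called lower in 2C, as median and quartiles per library (4.76 in mESC, 5.31 in the later TLSC C57/SPR library). Open squares mark the median of all genes.

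Later against earlier passage within the 4 TLSC libraries (2 against 2, line in the fit) gave 0 genes higher and 1 lower of 19241, with 834 at unadjusted p under 0.05 and 20 called by DESeq2, which did not include the 1 from edgeR. The gene was Snord82, a small nucleolar RNA chosen for naming after its values were seen, with 0 counts later against 5.44 ± 5.58 CPM earlier (at least 106-fold lower, adjusted p = 0.0254). No other named gene was called. Zscan4c stood at 1086 ± 532 against 531 ± 502 CPM (log2 1.38, SE 0.80), Zfp352 at log2 1.64 (SE 0.74), and Tcstv3 at 1.66 (SE 0.82). Tcstv1 stood at 1.63 (SE 0.72), Duxf3 at 0.25 (SE 0.51) and Dnmt3b at -1.33 (SE 0.56).

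As a list, 2C and MERVL genes were higher at the later passage with 0 of 37 members called (median log2 1.58; adjusted p = 1.91e-28, and 0.707 with an estimated correlation). The median was 3.02 in C57/SPR and 0.02 in 2C, a difference between lines that was not tested. With 2 lines and 1 residual degree of freedom, the camera p-values of this comparison could not show that a shift recurs with passage. Ribosomal protein genes (0.66; adjusted p = 2.35e-10), mitochondrially encoded genes (1.00; adjusted p = 0.000197) and oocyte genes (0.64; adjusted p = 0.00637) were higher with 0 called, each at 0.707 with an estimated correlation, and oxidative phosphorylation genes (0.39; adjusted p = 0.0122) at 0.714. The ribosomal and oxidative phosphorylation values came from C57/SPR, since in line 2C their medians were -0.13 (21 of 82 positive) and -0.16 (6 of 29 positive). Over 5 classes of genes by length the median log2 difference in C57/SPR ran from 0.73 for the shortest to -0.58 for the longest. After matching on length and expression the ribosomal, oxidative phosphorylation and mitochondrial medians in C57/SPR went from 1.39, 0.83 and 1.36 to 0.60, 0.25 and 0.16. Fibroblast genes (-1.01; adjusted p = 1.44e-08), formative genes (-0.57; adjusted p = 0.000136), and DNA methylation enzymes (-0.70; adjusted p = 0.00193) were lower with 0 called. WNT targets (-0.32; adjusted p = 0.0484), ERK targets (-0.30; adjusted p = 0.0113) and imprinted genes (-0.35; adjusted p = 0.0451) were lower with 0 called. Each of these 6 lists stood at adjusted p = 0.707 with an estimated correlation, and the WNT call was lost with relative log expression scaling (0.0503). The same matching moved the C57/SPR medians of WNT targets from -0.17 to 0.16 and of imprinted genes from -0.23 to 0.18, which changed their sign. It moved fibroblast genes from -0.95 to -0.38, formative genes from -0.87 to -0.40, DNA methylation enzymes from -0.76 to -0.37, ERK targets from -0.33 to -0.51 and oocyte genes from 0.80 to 0.35.

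In the 2CLC library against mESC of line C57/SPR (1 against 1, no test; log2 values with a prior count of 2, which draws them towards 0), Stra8 stood at 89.9 against 0.235 CPM (log2 8.27) and Sycp1 at 145 against 1.15 CPM (6.91). The 2C genes were low in both. Zscan4c had 2.51 against 0.157 CPM (3.58), Zscan4d 3.43 against 0.209 CPM (3.71) and Zfp352 1.54 CPM against 0 (at least 19.6-fold). Tcstv1 had 0.662 CPM against 0 (at least 8.44-fold) and Tcstv3 a ratio of 25.3 (8.37 to 125). Col3a1, with 0 counts in mESC, was at least 134-fold higher, and Robo4 (an endothelial guidance receptor gene), Col1a2 and Gata6 had ratios of 374 (103 to 3096), 260 (71.6 to 2151) and 36.2 (9.69 to 304). Nxpe5 was higher by log2 6.52. Lower were Ido2, of tryptophan breakdown (log2 -4.62), Acnat2, an acyltransferase gene (-3.88), Aldh1a3 (-3.34), Patl2, an oocyte RNA-binding gene (-3.22), Abcg1, a cholesterol exporter gene (-3.13), and Spi1, of the blood factor PU.1 (-3.10). Pou5f1 (-0.20) and Nanog (0.14) were close in the 2 libraries. Among 10665 genes with a mean of at least 5 CPM, 179 were at least 4-fold higher and 54 at least 4-fold lower. Against 10000 random lists matched on expression, the 2C and MERVL list (median 3.58), the germline list (3.91), the fibroblast list (3.16) and the cell cycle list (0.38) lay at percentile 100. ERK targets (0.43) lay at 99.7, and oxidative phosphorylation (-0.23), ribosomal protein (-0.14) and mitochondrially encoded genes (-0.35) at 0.0900, 0.25 and 0.560.

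The rESC and mESC libraries (1 against 1, no test) differed little. Sycp1 stood at 13.9 against 1.15 CPM (log2 3.53), Col2a1, a cartilage collagen gene, at 1.91, Dazl at 1.74, and Dmrtc2, a testis gene, at 1.63. Mir6236 stood at 1.63 and Ano1, a chloride channel gene, at 1.56. Firre, a long noncoding RNA of the X chromosome, was lower at 9.68 against 57.9 CPM (-2.57). Also lower were the neuronal RNA Bc1 (-1.75), Lexm (-1.65), the metal transporter Slc11a1 (-1.63), the splicing factor Rbm20 (-1.54) and the neural factor Pou4f2 (-1.50). Pou5f1 had 816 against 817 CPM, and Duxf3 0 counts in both. Of 10489 genes with a mean of at least 5 CPM, 1 was at least 4-fold higher and 2 lower. The germline list (median 1.03) lay at percentile 100 of random lists, the fibroblast list (0.64) at 100, ribosomal protein genes (0.07) at 99.7, the stress response list (-0.14) at 0.0400 and the formative list (-0.19) at 0.410.

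Across genes, the log2 folds of TLSC 2C over rESC and of 2CLC over mESC, which share no library, correlated with Pearson 0.388 and Spearman 0.383 (covariance 0.923). Simulation with no effect gave a correlation of -0.00102, a value near 0 by design since the simulated libraries were independent. Both folds set cells in another medium against ESC in 2i, so a shared effect of leaving 2i could not be told apart from a shared cell state. Zscan4c (12.28 for TLSC of both lines over rESC, 3.58 for 2CLC over mESC) and Sycp1 were among genes that differed the same way in both. The folds of TLSC C57/SPR and of 2CLC over their shared mESC library correlated at 0.565 (Spearman 0.561), where 50 simulations with no effect gave 0.574 from the shared library alone. The covariance was 1.24 against 0.565 simulated, a difference of 0.680. Genes are not replicates, so these values carry no p.

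By the GENCODE vM21 annotation of GRCm38, Duxf3 (ENSMUSG00000075046) lies on chromosome 10 at 58229979 to 58232675, Zscan4c (ENSMUSG00000054272) on chromosome 7 at 11005745 to 11010547 and Zscan4d (ENSMUSG00000090714) beside it at 11161374 to 11166159. Zfp352 (ENSMUSG00000070902) lies on chromosome 4 at 90218820 to 90225702, Pou5f1 (ENSMUSG00000024406) on 17 at 35506018 to 35510772, Trpm1 (ENSMUSG00000030523) on 7 at 64153835 to 64269775 and Sycp1 (ENSMUSG00000027855) on 3 at 102818499 to 102936100. Tbx3 (ENSMUSG00000018604) lies on chromosome 5 at 119670669 to 119684724, Dnmt3b (ENSMUSG00000027478) on 2 at 153649450 to 153687730, Eif2s3y (ENSMUSG00000069049) on Y at 1010543 to 1028847 and Snord82 (ENSMUSG00000064823) on 1 at 86356261 to 86356330. The strand of counting was not given, so counts of genes that overlap others could include antisense reads.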

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

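The tests of pseudogene values per library and of the scaling were chosen only after the result was seen. In the 4 TLSC libraries, 83 values (shares of counts, list means and named genes) were each checked for 1 library far from the other 3, as a gap over the range above the critical value of the Dixon test at 95%. Of these 12 passed, but the rate of about 1 in 20 by chance holds for independent normal values. These libraries were 2 lines at 2 passages and many values came from related genes, so 12 of 83 could not be set against that rate. In 9 of the 12 the later C57/SPR library was the distant one. In that library Zfp352 stood at 950 CPM against 96.3 to 130 in the others (ratio 0.961), Tcstv3 at 1343 against 117 to 279 (0.868) and BC147527 at 667 against 44.0 to 122 (0.874). Fam90a1a stood at 194 CPM against 19.4 to 29.1 (0.944), Ighv1-60 at 179 against 19.8 to 35.6 (0.901) and Dppa2 at 508 against 152 to 198 (0.870). Its share on processed pseudogenes was 2.65% against 1.08% to 1.20% (0.922), its mean log2 CPM of repressors of the 2C programme 6.89 against 7.20 to 7.22 (0.928) and of JAK/STAT3 genes 4.10 against 4.51 to 4.56 (0.879). Tfcp2l1 was distant in the earlier C57/SPR library, at 404 CPM against 83.6 to 115 (0.901). In the earlier 2C library Cdx2 stood at 1.40 CPM against 0.104 to 0.196 (0.929) and glycolysis genes at a mean log2 CPM of 8.58 against 9.14 to 9.23 (0.863). Core and naive pluripotency genes moved with passage in opposite ways, by a median log2 of -0.27 in C57/SPR and 0.34 in 2C (difference -0.603), the only 1 of 25 lists to do so with both medians at least 0.25 from 0, and this difference was not tested.

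The 2C and MERVL genes were higher in the later than the earlier C57/SPR library by a median log2 of 3.02, against 0.02 between the 2C libraries. A length trend as the whole cause was argued against by genes of like length and expression: after their median was taken off, the list kept 2.32 (quartiles 1.97 to 2.48). The choice of scaling did not account for it either, since the lower of the 2 other scalings still gave 3.07. The median of all genes was -0.049 with TMM and 0.054 with relative log expression, so these scalings could move the list only a little. An effect of composition that they share could not be decided. A larger share of cells in the 2-cell-like state, passage itself and chance between single libraries stayed open and untested.

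The 411 processed pseudogenes called lower in TLSC 2C than in TLSC C57/SPR were also high in the mESC and 2CLC libraries of C57/SPR, where the lower of the 2 medians stood log2 4.70 above TLSC 2C, which was needed if a sequence variant of the C57/SPR line moved reads onto pseudogene copies whatever the culture. They were as high in rESC (median 4.78, 379 of 411 above TLSC 2C), whose line was not given. The Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty had 0 counts in rESC, 0 to 4 in TLSC C57/SPR libraries and 686 to 2235 in TLSC 2C libraries. In these genes rESC was like C57/SPR and unlike 2C, so it may not stand for another line. A trait of the 2C line alone would give these pseudogene values too. The later C57/SPR library as the whole cause was argued against by the earlier one: over the 711 pseudogenes called with it left out, it stood 3.37 above TLSC 2C (quartiles 2.00 to 4.78). All of these genes were chosen for low values in TLSC 2C, which raises every such difference, and over all 2006 tested the medians were 0.69 in mESC, 0.76 in 2CLC, 0.78 and 1.64 in the earlier and later C57/SPR libraries and 0.79 in rESC. Expression of these pseudogenes that differs between lines would give the same values and stayed open.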

How the results depend on the processing

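The settings with C57/SPR as the only TLSC line, with protein-coding genes only and the gene lists with a library left out were chosen after the result was seen. Of 3317 values of named genes under an alternative, 2608 kept their direction and side of the threshold, 625 lost the call, 62 gained one and 22 changed sign. DESeq2 called 5228 genes in TLSC against ESC in 2i medium (edgeR 2545), 2811 against mESC (1542), 1520 against 2CLC (629), 3757 against rESC (2232) and 20 between passages (1). With no filter edgeR called 2796 against mESC, 1620 against 2CLC, 3741 against rESC, 2428 between lines (1279; DESeq2 1899) and 19 between passages. Relative log expression scaling gave 14 between passages. The deposited TPM with limma called 1150 in TLSC against ESC in 2i medium with a pseudocount of 1 and 666 on all genes above 0, but 0 against mESC in all 3 settings (2611, 3259 and 3805 at unadjusted p under 0.05; edgeR on counts 1542, DESeq2 2811). For rESC they called 0 in all 3 (3288, 4009 and 4679; edgeR 2232, DESeq2 3757), and for 2CLC 0, 0 and 166 (1 higher and 165 lower, 1 shared with the main calls; 1881 and 2341; edgeR 629, DESeq2 1520). Between lines they called 61, 0 and 0 (3002 and 4142; edgeR 1279, DESeq2 1899), and between passages 9, 24 and 4. With the lines and both ESC libraries as separate groups TLSC against ESC in 2i medium gave 4948, and with C57/SPR as the only TLSC line 4150, and 1454 against rESC. With all 4 TLSC libraries as 1 group edgeR called 0 against mESC (3805 at unadjusted p under 0.05; DESeq2 2781) and 0 against 2CLC (2147; DESeq2 1388). Without a term for the line edgeR called 0 between passages (133; DESeq2 3). Protein-coding genes alone gave 205 against 2CLC and 487 between lines, from fewer genes tested. With 1 library left out, called genes ran from 0 to 4364 in TLSC against ESC in 2i medium (edgeR gave 0 without mESC and without rESC, with 3743 and 3765 at unadjusted p under 0.05 and 2910 and 2835 by DESeq2). They ran from 4527 to 6391 against mESC, 1745 to 4890 against 2CLC, 1860 to 7141 against rESC and 773 to 5993 between lines, and the passage test could not be fitted. Lists called ran from 5 to 8 of 25, 4 to 6, 5 without either library, 6 to 9 and 4 to 13 in that order, and 0 of 150 list tests were called with an estimated correlation (39 with the preset). Genes of at least 10 CPM gave a fold correlation of 0.587, and the comparisons of 1 library with 1 gave 237 and 172 genes (2CLC) and 3 and 2 (rESC) under their alternatives. Signs changed in TLSC against ESC in 2i medium for Cdx2 (-1.03 without the earlier 2C library, the others left out giving up to 1.55, and -0.84 with C57/SPR only), Dnmt3b (-1.54) and Nanog (0.17, both with C57/SPR only). With all 4 TLSC libraries they changed against mESC for Nanog (-0.44) and Dnmt3b (0.63) and against 2CLC for Dnmt3b (1.00), with C57/SPR only against rESC for Nanog (0.20), and without a line term for Gata6 between passages (-0.47). Between lines Zscan4c gave 0.92, 0.92 and 0.92 and Tcstv1 0.46, 0.47 and 0.46 with TPM. Cdx2 ran from -0.70 (without the earlier 2C library) to 3.00 (without the later). Without the earlier and the later C57/SPR library Zscan4d gave -0.085 and 2.74, Sox2 0.50 and -0.91, Zscan4c -0.89 and 2.23, Tcstv1 -1.46 and 1.88, Tcstv3 -2.39 and 1.18 and Zfp352 -2.91 and 0.44. The cause was not tested for these changes apart from the fewer genes or libraries named. Values under 0.0683 to 0.147 CPM were beyond the depth of these libraries, and no paired analysis was possible because the labels give no numbers that pair libraries across groups.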

Other observations

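The gene families below, their tests and the split of fibroblast genes by their level in 2i were chosen only after the result was seen, while the other 2 fibroblast tests were chosen before. In TLSC against ESC in 2i medium Obox genes, oocyte homeobox genes outside the 2C list, had 12 of 36 genes higher and 0 lower (median log2 10.66; adjusted p = 3.56e-12 over 17 families, and 0.244 with an estimated correlation). Of the 12, 11 were annotated as pseudogenes or named so, and Obox3, which was not, rose at least 1197-fold from 0 counts (229-fold without the later C57/SPR library). Leaving out that library gave 21 of 34 Obox genes higher (median 9.21), and leaving out the earlier C57/SPR library gave 9 of 36 (10.98). Rhox, homeobox genes of the reproductive tract, rose with 8 of 24 higher (5.51; adjusted p = 1.08e-09, and 0.210 with an estimated correlation) and Mage, cancer-testis genes, with 9 of 26 higher, 8 of them X-linked (5.48; adjusted p = 9.65e-07, and 0.153 with an estimated correlation). Xlr, germ cell chromatin genes, rose with 9 of 15 higher (5.23; adjusted p = 1.42e-08, and 0.132 with an estimated correlation), as in Xlr3b (log2 5.07, adjusted p = 0.0110). Histone genes had 9 of 56 higher and 0 lower (4.13; adjusted p = 7.43e-11, and 0.275 with an estimated correlation), as in Hist1h4i (5.63, adjusted p = 0.0177). Collagens had 14 of 44 higher and 0 lower (3.47; adjusted p = 1.27e-09, and 0.132 with an estimated correlation), as in Col22a1 (4.84, adjusted p = 0.0110). Zinc finger genes named Zfp fell with 6 of 357 higher and 19 lower (-0.28; adjusted p = 0.000223, and 0.226 with an estimated correlation). Olfactory receptor genes rose as well, with 21 of 119 higher and 1 lower (5.76; adjusted p = 2.75e-07, and 0.153 with an estimated correlation). Vomeronasal receptor genes had 8 of 54 higher and 0 lower (5.40; adjusted p = 0.00125, and 0.222 with an estimated correlation). Hox, keratin and Cyp genes rose too (3.59, 3.09 and 1.66), so the rise was not particular to germ cell families. Slc transporter genes had 34 of 328 higher and 17 lower and were not called (adjusted p = 0.560). The amino acid transporter gene Slc43a1 was higher by log2 3.70 (adjusted p = 0.00810). Without mESC or without rESC edgeR called 0 genes in this comparison (3743 and 3765 at unadjusted p under 0.05; DESeq2 2910 and 2835). Obox genes were also higher in TLSC C57/SPR than in 2CLC (23 of 36; adjusted p = 2.69e-30, and 0.252 with an estimated correlation). They were lower in TLSC 2C than in TLSC C57/SPR (14 of 36; -3.45; adjusted p = 9.13e-12, and 0.769 with an estimated correlation). The later C57/SPR library carried most of that size, since the median was -0.65 without it and -4.28 without the earlier C57/SPR library. In the earlier C57/SPR library 10 of the 36 lay below both 2C libraries. Of the 14 called 0 did, which their choice for low values in 2C made likely.

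Fibroblast genes were present in the TPSC and KOSR libraries, and Lox, Col3a1 and Postn were near 0 in 2i. RNA of fibroblasts in the culture would bring other abundant fibroblast transcripts, and of a second list of 18 such genes 77.8% (14) lay above both 2i libraries in all 5 TPSC and KOSR libraries. That list summed to 517 and 274 CPM in TLSC 2C, 312 and 200 in TLSC C57/SPR and 252 in 2CLC, against 102 in mESC and 128 in rESC. The first list summed to 1671 and 1388, 2095 and 1304, and 1609 CPM in the same order against 1864 in mESC and 1972 in rESC, so only 1 of the 5 sums exceeded those in 2i. A single fixed profile present at another share in each library could not be decided. Of 10 pairs of libraries 6 had an interquartile range of member ratios of 1 or more. Members also expressed in 2i (6 of 20 on the first list at 1 CPM or more) keep a baseline that widens the ranges, and the 6 genes of low baseline gave 3 of 10 pairs. The labels name no feeder cells, and cells of a mesenchymal kind arising in these media would give the same values, which stayed open and untested.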
